A study of Mus musculus with 6 samples.

How the data were processed

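RNA was measured in 6 libraries of sorted mouse cells, 3 from animals given vehicle and 3 from animals given 15-HETrE. Per the labels' protocols, the peri-infarct cortex was taken 4 days after 60 min of middle cerebral artery occlusion and dissociated with pronase for 75 min. RNA was purified with the RNeasy Mini kit and libraries were made with the Ovation SoLo kit, a low-input method. Per the submitters' processing notes, Trimmomatic, HISAT2, featureCounts and edgeR were used with the mm10 mouse genome; their versions, settings and gene annotation are not given in the sources used here.

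The deposited table holds 24419 gene symbols and 6 columns of a signal that the authors scaled as CPM, reads relative to the library's total, with a size factor for each library, as the values show. The column sums lie between 960982 and 1080350 and so differ between libraries, as they do after edgeR's scaling factors are applied, and the factors they imply have a geometric mean of 1. The value of 1 read was taken in each column as the smallest value above 0, 0.0450 to 0.180 CPM. In every column, 100% of the values were whole multiples of it within a tolerance of 1e-04 reads. The test written before the data were examined assumed CPM; the same test was applied to the scaled CPM. The libraries were assigned to groups by column names, which give the group of each. The numbers 1 and 2 in vehicle and 1 in 15-HETrE match the sample titles; the others carry no number, and they are called 15-HETrE unnumbered, vehicle combined and 15-HETrE combined here. What combined and the prefixes of the names stand for is not given in the sources used here. The number of other columns was 0. Depth per library is the sum of recovered reads over genes, 5405245 to 22558400, and the floor for a gene with no read is 3 counts. Reads are not counted by molecular identifiers, so floors cover counting error only.

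Genes with a mean of at least 1 CPM over all 6 libraries were kept (14523). Values were taken as log2(CPM + 1), with a pseudocount of 1, and fitted with limma 3.58.1 in R 4.3.3 with the treatment group as the only term and a trend of the variance on the mean. Fold changes are 15-HETrE minus vehicle on this scale, which understates the change of low genes. The test is two-sided with Benjamini-Hochberg adjustment over all genes kept and a threshold of 0.05. Standard deviations are over the 3 libraries of a group, in CPM.

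Gene lists were fixed before the data were examined, 14 of cell type markers and 26 of functions. The marker lists cover pan-neuronal, excitatory and inhibitory neuron, astrocyte, microglia, monocyte and neutrophil, lymphocyte, oligodendrocyte, precursor, endothelial, pericyte, fibroblast, ependymal and erythrocyte genes. Each list with at least 3 genes kept, 34 in all, was tested with camera at a preset correlation of 0.01, with adjustment over the 34 lists. Counts of genes "adjusted over the list alone" use the same gene p-values. The mean level of each marker list was compared by an exact two-sided permutation test over the libraries. Mitochondrially encoded genes were not analysed here.

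The genes named follow a rule fixed in advance. It takes Padi4, Pla2g2e, Alox15 and Thy1; up to 10 genes per direction with the largest fold change among those that pass, with a mean of at least 5 CPM and no overlap between groups, filled up to 5 by the smallest p where fewer pass, without predicted genes, pseudogenes and genes of X inactivation or the Y chromosome; up to 4 members of each list with the smallest p; and the 5 genes with the highest mean. As no gene passed, the genes of the direction part are the 5 with the smallest p on each side. Some genes that the rule takes are not reported here.

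Positions are from GENCODE M21 on GRCm38, the assembly that mm10 names; 23350 of the 24419 symbols matched directly, 669 through older symbols, and 23976 had a single position. Transcript length and GC content come from the same annotation.

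Alternatives planned in advance were pseudocounts of 0.5, 0.1 and 5, no filter and a filter at 5 CPM, rescaling by TMM, by median-of-ratios factors, by quantiles and without ribosomal RNA and hemoglobin genes, library weights, a robust trend, leaving out each library, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, camera with an estimated correlation or ranks, and fry. Those added after the data were seen were a batch term for the name prefix, leaving out both combined libraries, centring on transcript length or GC content, and the fibroblast level as a covariate.

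The scripts were tested on simulated counts with the real means and library sizes, in 3 runs over 14523 genes with changes of known size. Of genes changed 4-fold, limma found 28.7%, edgeR 24.7% and DESeq2 54.7%; false calls were 26 of 260 for limma, 10 of 239 for edgeR and 182 of 503 for DESeq2. Among simulated lists of independent genes, 60 of 60 shifted lists and 1 of 300 unshifted lists were called. Estimated correlations within the real lists ran from -0.02 for growth factor genes to 0.91 for astrocyte markers. The rate of false calls among independent genes does not carry over to correlated lists.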

Results

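Cells of the cortex around an infarct, sorted as neurons, were profiled 4 days after a stroke in mice. Transient ischemia was produced in male C57BL/6N mice by occluding the middle cerebral artery for 60 min. The animals then received intravenous 15-HETrE, a hydroxylated fatty acid made from dihomo-gamma-linolenic acid, or vehicle. Injections were given at 24, 48 and 72 h after onset, each in 150 µL of phosphate-buffered saline, and 600 ng of the lipid was used. Cells of the peri-infarct cortex were sorted for Thy1 on the surface and for the absence of ACSA2, CD31, CD45 and O4, the surface antigens of astrocytes, endothelium, leukocytes and oligodendrocyte-lineage cells. Each group was represented by 3 RNA-seq libraries. The labels do not say that each library came from a separate animal, so the p-values below measure the spread between these libraries, which may be technical.

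The 6 libraries held between 5405245 and 22558400 reads assigned to genes. Vehicle 1, vehicle 2 and vehicle combined held 22558400, 21365984 and 5405245 reads. The 15-HETrE library numbered 1 held 21324527 reads, the 15-HETrE library without a number held 16218335 and 15-HETrE combined held 7993084. Genes with at least 1 read numbered 13763 to 17915 per library. Within the vehicle group, vehicle 1 and vehicle 2 correlated at r = 0.970 across genes on the log2 scale, while all other pairs of libraries lay between 0.817 and 0.919. Vehicle combined correlated with vehicle 1 and vehicle 2 at 0.818 and 0.820. Vehicle 1 and vehicle 2 reached 0.889 to 0.919 with 15-HETrE 1 and 15-HETrE unnumbered. Genes are not independent replicates, so these coefficients only describe the libraries. The column names carried 3 prefixes: vehicle 1, vehicle 2 and 15-HETrE 1 shared the first, 15-HETrE unnumbered had the second, and a library of each group was named combined. Differences within the first prefix and within the combined pair are given below as within-prefix values. For a list they are differences of the mean over its members, an unlike measure to the median given with its call. The second prefix held a single library, so it gave no difference.

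The comparison asked which transcripts differ between sorted peri-infarct cells of mice given 15-HETrE and of mice given vehicle. Although sorted as neurons, the libraries held oligodendrocyte markers at 9.28 to 10.4 and pan-neuronal markers at 6.73 to 8.17 (mean log2 scale). The lists hold different genes, so these levels do not compare the shares of the cells. As groups, transcripts of neuronal, synaptic and ion channel genes rose in the 15-HETrE libraries by medians of 0.56 to 0.81 on the log2 scale, and those of cell cycle and extracellular matrix genes fell, with medians of -1.70 and -2.20. The rise was not particular to neuronal genes. Astrocyte markers, of cells the sort was meant to leave out, had the highest median of the 34 lists, 1.04. Every one of the 22 list calls, out of 34 lists, was lost when the correlation between genes was estimated from the libraries, with a smallest adjusted p = 0.276 with an estimated correlation (camera). Mki67, a marker of dividing cells, had 249 ± 21.1 CPM in vehicle and 55.3 ± 16 CPM in 15-HETrE libraries (SD, n = 3 per group), and no single gene passed limma's test over all genes. The libraries also differed in transcripts of other cell types, with fibroblast and matrix transcripts abundant in vehicle 1 and vehicle 2 and low in vehicle combined.

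Of 14523 genes tested, 0 were higher and 0 were lower in 15-HETrE at an adjusted p of 0.05 (limma), and the smallest adjusted p was 0.131. At an unadjusted p under 0.05, 620 genes were higher and 760 lower, 1380 together, where 726 would pass if p-values were evenly spread; the other 9 splits of the libraries into 3 and 3 gave 79 to 1815 such genes. edgeR's quasi-likelihood test on the recovered reads also called 0 genes in either direction and had 1232 genes at an unadjusted p under 0.05. DESeq2 on the same reads called 35 genes higher and 130 lower; in simulated data of this design, 182 of its 503 calls were false. The libraries of both groups did not overlap for 2202 genes, 15.2% of those tested, against the 10% that chance gives for 3 against 3. Without vehicle combined, limma called 2 genes higher and 108 lower, and with library weights, which gave that library the least weight, 1059 and 1366. Among alternatives added after the data were seen, the prefix as a batch term gave 1 gene higher and 7 lower (smallest adjusted p 0.0251, limma), and leaving out both combined libraries gave 3 and 201.

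Among genes whose libraries did not overlap, those with the smallest p on the higher side included synaptic and neurofilament genes, and none of them passed in limma or edgeR. Dmtn, which encodes an actin-bundling protein (chromosome 14, 70601263 to 70636048, GRCm38), had 35.9 ± 12.1 CPM in vehicle and 114 ± 21.2 CPM in 15-HETrE libraries, a log2 fold change of 1.67 (SE 0.31, adjusted p 0.334, limma). Lynx1, a membrane-anchored modulator of nicotinic acetylcholine receptors (chromosome 15, 74747852 to 74753046), stood at 54.7 ± 11.1 and 157 ± 39.9 CPM. Unc13a, which primes synaptic vesicles for release, stood at 90.4 ± 11.7 and 217 ± 53.9 CPM. Cacng2, which encodes stargazin, an auxiliary subunit of AMPA receptors, stood at 11.3 ± 4.61 and 44.6 ± 6.12 CPM, and Nefl, the neurofilament light chain, at 66.3 ± 29.4 and 249 ± 111 CPM. The log2 fold changes of Lynx1, Unc13a, Cacng2 and Nefl were 1.49, 1.23, 1.95 and 1.92, each with an adjusted p of 0.334 (limma). Within the first prefix these 5 genes differed by 1.30 to 1.94, and within the combined pair by 1.13 to 2.65; as they were chosen for no overlap in the same libraries, their sign there was fixed. Over all 14523 genes the differences within the first prefix and within the combined pair correlated at r = 0.186 (across genes, which are not independent replicates).

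On the lower side, Mki67 (chromosome 7, 135689784 to 135716361) had the smallest p of all genes, with a log2 fold change of -2.18 (SE 0.27, adjusted p 0.131, limma). Its 3 vehicle libraries lay at 273, 240 and 233 CPM and its 3 15-HETrE libraries at 72.9, 41.7 and 51.2 CPM. Colec12, a scavenger receptor of the collectin family (chromosome 18, 9707595 to 9882644), stood at 78.3 ± 26.1 CPM in vehicle and 9.05 ± 2.49 CPM in 15-HETrE libraries, a log2 fold change of -2.95 (SE 0.41, adjusted p 0.190, limma). Rai14, Hk2 (a hexokinase) and Gtse1 (expressed in dividing cells) had log2 fold changes of -2.73, -3.48 and -3.52, each with an adjusted p of 0.334 (limma). Gtse1 was supported by 288, 322 and 92 reads in the vehicle libraries and by 27, 3 and 0 reads in the 15-HETrE libraries. Within the first prefix these 5 genes differed by -4.11 to -1.80, and within the combined pair by -4.13 to -1.95, with the sign fixed by the same choice. In DESeq2, all 10 genes of both sides passed, with adjusted p from 1.91e-09 for Colec12 to 0.00627 for Nefl. They were chosen for small p and no overlap in the same libraries, so this is no independent evidence. In simulated data, 182 of 503 DESeq2 calls were false.

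**Figure D1:**
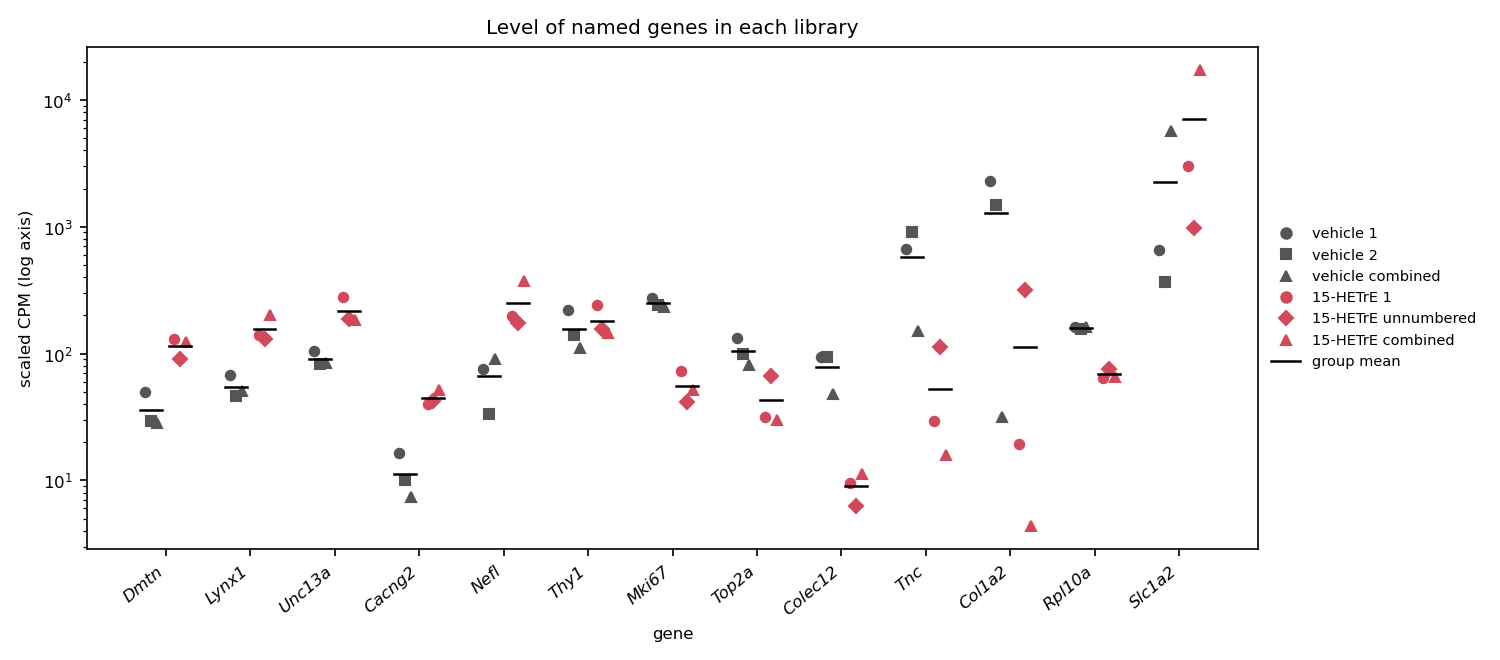
Level of 13 named genes in each of the 6 libraries, in scaled CPM on a log axis; grey points are vehicle and red points 15-HETrE libraries, the shape gives the library, and black lines are group means. Mki67 lies between 233 and 273 CPM in vehicle and between 41.7 and 72.9 CPM in 15-HETrE libraries, while Col1a2 spans from 31.8 to 2307 CPM within vehicle.

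Neuronal gene lists rose in the 15-HETrE libraries. Pan-neuronal markers were higher for 15 of 16 genes with a median log2 fold change of 0.80 (camera adjusted p 7.43e-07), presynaptic genes for 21 of 22 with a median of 0.80 (camera adjusted p 4.48e-10), postsynaptic genes for 24 of 25 with a median of 0.72 (camera adjusted p 1.05e-10) and voltage-gated channels for 18 of 21 with a median of 0.71 (camera adjusted p 1.65e-08). For these 4 lists the call was lost, at adjusted p = 0.276 with an estimated correlation (camera). No member passed over all genes; adjusted over the list alone, 3 pan-neuronal, 1 presynaptic, 0 postsynaptic and 4 channel genes passed. Rbfox3, which encodes the nuclear antigen NeuN, had 74.5 ± 29.1 CPM in vehicle and 160 ± 39.8 CPM in 15-HETrE libraries. Cplx2, a regulator of vesicle fusion, had 253 ± 83.9 and 724 ± 396 CPM, and Bsn, a scaffold of the presynaptic active zone, had 359 ± 100 and 791 ± 307 CPM. Homer1, a scaffold of the postsynaptic density, had a log2 fold change of 0.80. Cacna1a, a presynaptic calcium channel, had 114 ± 19.0 and 221 ± 33.3 CPM. As means over the members, the pan-neuronal list differed by 0.80 in all libraries, 1.03 within the first prefix and 0.97 within the combined pair; the presynaptic list differed by 0.81, 1.05 and 1.06, the postsynaptic list by 0.81, 1.17 and 0.73, and the channels by 0.62, 0.92 and 0.47. Beside them, the fibroblast markers differed by -3.60 within the first prefix and by -0.13 within the combined pair, and the astrocyte markers by 0.79 in all libraries, 0.93 within the first prefix and 1.03 within the combined pair. 15-HETrE unnumbered enters neither within-prefix value. Vehicle 1 lay above it on the pan-neuronal list, at 7.565 against 7.555, and on the presynaptic list, at 7.85 against 7.78 (mean log2 scale). The levels of these lists thus overlapped between groups, while those of the postsynaptic and channel lists did not. Of the pan-neuronal genes, 5 stand also on another list.

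Both excitatory and inhibitory markers moved up. All 14 excitatory neuron markers were higher, with a median of 0.81 (camera adjusted p 3.95e-05), and 11 of 14 inhibitory neuron markers, with a median of 0.56 (camera adjusted p 0.0128). Both calls were lost, at adjusted p = 0.298 with an estimated correlation (camera). Adjusted over the list alone, 0 genes of either list passed, as over all genes. Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, had 138 ± 101 CPM in vehicle and 306 ± 40.4 CPM in 15-HETrE libraries, and Cux2, of upper-layer neurons, had 63.1 ± 23.6 and 131 ± 24.0 CPM. The interneuron genes Lamp5 and Vip had log2 fold changes of 1.22 and 1.13, with overlapping libraries. The excitatory list differed by 1.06 within the first prefix and 1.51 within the combined pair, and the inhibitory list by 0.65 and 0.63. 15-HETrE unnumbered, in neither value, stood at 5.83 on the excitatory list, under vehicle 1 at 6.29 (mean log2 scale). The inhibitory list did not overlap between groups. The excitatory median was 1.33 without vehicle 1 and 0.52 without 15-HETrE 1, past the test in both. The inhibitory call was lost without vehicle combined (median 0.32, camera adjusted p 0.0520) and without 15-HETrE 1 (median 0.27, camera adjusted p 0.110), and the median was 0.36 without 15-HETrE combined. Genes of axon guidance and the neuronal cytoskeleton were higher for 24 of 29 members, with a median of 0.36 (camera adjusted p 0.00241; adjusted p = 0.298 with an estimated correlation). Of these, 0 passed adjusted over the list alone or over all genes; Dcx, a microtubule protein of migrating neurons, had 40.5 ± 5.07 and 73.8 ± 16.1 CPM. The axon guidance list differed by 0.39 within the first prefix and 0.34 within the combined pair.

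Cell cycle genes fell. All 20 listed genes were lower in 15-HETrE libraries, with a median log2 fold change of -1.70 (camera adjusted p 1.35e-11; adjusted p = 0.276 with an estimated correlation). Adjusted over the list alone, 11 of the 20 passed, against 0 over all genes. Besides Mki67, Top2a, a topoisomerase used in mitosis, had 105 ± 26.1 CPM in vehicle and 42.8 ± 20.5 CPM in 15-HETrE libraries. Mcm6, of the replicative helicase, had 61.5 ± 9.97 and 18.5 ± 9.0 CPM, and the cyclin gene Ccna2 had 42.2 ± 18.1 and 9.81 ± 6.14 CPM. The libraries of the groups did not overlap for these 4 genes, but they were taken for the smallest p of the list, which favours no overlap. The mean of the list did not overlap either. It lay at 5.11, 5.11 and 3.89 in the vehicle libraries and at 3.48, 3.39 and 2.57 in the 15-HETrE libraries (log2 scale). The list differed by -1.62 within the first prefix and by -1.32 within the combined pair, where the fibroblast markers differed by -3.60 and -0.13. Which of the sorted cells carried these transcripts was not tested, so the fall cannot be placed in neurons.

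Genes of the extracellular matrix fell, with a wide spread inside the vehicle group. Of 26 matrix genes, 22 were lower, with a median of -2.20 (camera adjusted p 8.9e-09; adjusted p = 0.298 with an estimated correlation), and adjusted over the list alone 7 passed, against 0 over all genes. Fibroblast markers were lower for 9 of 10 genes with a median of -1.86 (camera adjusted p 0.0108; adjusted p = 0.431 with an estimated correlation), and 0 passed adjusted over the list alone or over all genes. The lists share 4 genes. Tnc, a matrix glycoprotein of injured tissue, had 576 ± 386 CPM in vehicle and 52.9 ± 52.9 CPM in 15-HETrE libraries, Timp1, a metalloproteinase inhibitor, had 53.4 ± 43.9 and 1.78 ± 1.82 CPM, and Lamb1, a laminin chain, had 197 ± 130 and 28.1 ± 12.6 CPM. Col1a2, a chain of type I collagen, stood at 2307, 1482 and 31.8 CPM in vehicle 1, vehicle 2 and vehicle combined, and at 19.2, 315 and 4.33 CPM in 15-HETrE 1, unnumbered and combined. Within the first prefix the matrix list differed by -3.30 and the fibroblast list by -3.60, and within the combined pair by -0.50 and -0.13. The fibroblast call was lost without vehicle 1 (median -0.72, camera adjusted p 0.0818) and with no filter on low values (camera adjusted p 0.0623). Its median was -1.02 without vehicle 2, -3.72 without vehicle combined, -3.16 without 15-HETrE unnumbered and -1.14 without 15-HETrE combined, and the matrix median was -1.45 without vehicle 2 and -3.40 without vehicle combined. Thy1, the marker used for the sort, is also carried by fibroblasts.

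Pericyte and smooth muscle markers fell as well, 8 of 10 being lower with a median of -1.06 (camera adjusted p 0.00158; adjusted p = 0.298 with an estimated correlation). Adjusted over the list alone, 1 gene passed, against 0 over all genes. Pdgfrb, a receptor of mural cells and fibroblasts, had 261 ± 131 CPM in vehicle and 62.7 ± 34.4 CPM in 15-HETrE libraries, and Rgs5, a pericyte gene, had 192 ± 45.5 and 100 ± 52.7 CPM. The list differed by -1.56 within the first prefix and by -0.21 within the combined pair, beside the -3.60 and -0.13 of the fibroblast markers, and its median was -0.64 without 15-HETrE 1.

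Inflammatory and interferon genes went different ways. Cytokines, chemokines and their regulators were lower for 16 of 20 genes, with a median of -1.25 (camera adjusted p 0.00128; adjusted p = 0.276 with an estimated correlation), and adjusted over the list alone 3 passed, against 0 over all genes. The chemokines Ccl2 and Cxcl1 had 48.8 ± 34.2 and 161 ± 138 CPM in vehicle and 2.14 ± 2.86 and 7.91 ± 5.68 CPM in 15-HETrE libraries. In vehicle 1, vehicle 2 and vehicle combined Ccl2 stood at 46.4, 84.0 and 15.8 CPM and Cxcl1 at 187, 285 and 12.2 CPM. Il1a, which encodes interleukin-1 alpha, went against its list, with 0.120 ± 0.208 CPM in vehicle and 8.19 ± 3.80 CPM in 15-HETrE libraries, from 0, 8 and 0 reads and from 135, 98 and 93 reads. The list differed by -1.53 within the first prefix and by -0.36 within the combined pair, beside the -3.60 and -0.13 of the fibroblast markers. Its summed CPM was 2403, 2593 and 272 in the vehicle libraries and 184, 400 and 182 in the 15-HETrE libraries, and that of the fibroblast markers was 9277, 7241 and 1461 and 1179, 1782 and 1271, in the same order. Interferon-response genes were higher for 13 of 23 genes, with a median of 0.33 (camera adjusted p 0.0338; adjusted p = 0.479 with an estimated correlation), and adjusted over the list alone 2 passed, against 0 over all genes. The interferon-induced genes Ifit1, Ifit3 and Irf7 had log2 fold changes of 1.99, 1.29 and 1.66 with no overlap between groups. They were taken for small p, which favours no overlap, and 10 of the 23 members were lower. The interferon list differed by 0.78 within the first prefix and by 0.02 within the combined pair. Its call was lost without vehicle 1 (median 0.28, camera adjusted p 0.189), without 15-HETrE 1 (median -0.04, camera adjusted p 0.629) and without 15-HETrE unnumbered (median 0.23, camera adjusted p 0.0887), and its median was 0.65 without 15-HETrE combined. The interferon call was also lost with ranks (camera adjusted p 0.0809), with the prefix term (camera adjusted p 0.0540) and with the fibroblast level as a covariate (median 0.28, camera adjusted p 0.0704), the last 2 added after the data were seen.

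Lists of the stress response fell by smaller amounts. Heat shock genes were lower for 12 of 15 members with a median of -0.43 (camera adjusted p 3.55e-04; adjusted p = 0.276 with an estimated correlation), and adjusted over the list alone 2 passed. Genes of endoplasmic reticulum stress and the integrated stress response were lower for 17 of 20 with a median of -0.53 (camera adjusted p 6.11e-04; adjusted p = 0.298 with an estimated correlation), and 0 passed adjusted over the list alone. Antioxidant genes under Nrf2 were lower for 16 of 22 with a median of -0.53 (camera adjusted p 0.00162; adjusted p = 0.276 with an estimated correlation), and 0 passed adjusted over the list alone. Over all genes, 0 members of these 3 lists passed. Bag3, a co-chaperone, had 45.0 ± 18.4 CPM in vehicle and 10.2 ± 0.357 CPM in 15-HETrE libraries, Hspb1, a small heat shock protein, had 41.7 ± 15.0 and 9.26 ± 6.55 CPM, and Nfe2l2, which encodes Nrf2, had 76.6 ± 4.41 and 36.2 ± 13.5 CPM. As means over the members, the heat shock, reticulum stress and antioxidant lists differed by -0.69, -0.49 and -0.46 in all libraries. Within the first prefix these means differed by -0.79, -0.61 and -0.85, and within the combined pair by -0.61, -0.22 and 0.06. Beside them, the fibroblast markers differed by -3.60 within the first prefix and -0.13 within the combined pair. The heat shock median was -0.27 without vehicle 1 and -0.28 without 15-HETrE combined, the reticulum stress median was -0.30 without vehicle 2, and the antioxidant median was -0.32 without 15-HETrE 1. With the fibroblast level as a covariate the reticulum stress call was lost (median -0.29, camera adjusted p 0.0704).

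Regeneration-associated genes were lower for 15 of 21 members, with a median of -0.32 (camera adjusted p 0.00164; adjusted p = 0.276 with an estimated correlation), and the median was -0.48 without 15-HETrE 1. Of these genes 2 passed adjusted over the list alone, against 0 over all genes. The transcription factor genes Myc and Atf3, induced in neurons after axon injury, had 60.1 ± 6.01 and 56.5 ± 20.4 CPM in vehicle and 18.9 ± 4.93 and 23.2 ± 12.7 CPM in 15-HETrE libraries. As means over the members, the list differed by -0.61 in all libraries, -0.66 within the first prefix and -0.67 within the combined pair. Survival genes that act against apoptosis were lower for 12 of 16 members, with a median of -0.36 (camera adjusted p 0.0110; adjusted p = 0.276 with an estimated correlation), and adjusted over the list alone 1 passed, against 0 over all genes. Bcl2l1, an inhibitor of mitochondrial apoptosis, had 105 ± 7.65 and 63.3 ± 6.36 CPM. As a mean, the survival list differed by -0.50 in all libraries, -0.76 within the first prefix and -0.10 within the combined pair. Beside it, the fibroblast markers differed by -3.60 within the first prefix and -0.13 within the combined pair. The survival call was lost without 15-HETrE 1 (median -0.33, camera adjusted p 0.070) and without 15-HETrE unnumbered (median -0.47, camera adjusted p 0.0666).

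Immediate early genes and targets of PPAR, a nuclear receptor bound by fatty acids, fell by small medians. Immediate early genes were lower for 17 of 23 members with a median of -0.26 (camera adjusted p 0.0396; adjusted p = 0.479 with an estimated correlation), and 0 passed adjusted over the list alone or over all genes. Dusp5, a phosphatase gene, had 16.3 ± 5.19 CPM in vehicle and 3.18 ± 2.53 CPM in 15-HETrE libraries. Arc, a marker of synaptic activity, had a log2 fold change of 0.79 with overlapping libraries (adjusted p 0.513, limma). Arc differed by 0.90 within the first prefix and by 0.02 within the combined pair. The call was lost without vehicle 2 (median -0.08, camera adjusted p 0.431), without vehicle combined (median -0.31, camera adjusted p 0.0517), without 15-HETrE 1 (median -0.20, camera adjusted p 0.0753) and without 15-HETrE combined (median -0.16, camera adjusted p 0.119). It was also lost with no filter (camera adjusted p 0.0709), without both combined libraries (median -0.29, camera adjusted p 0.0629), with centring on transcript length (median -0.19, camera adjusted p 0.0640) and with the fibroblast covariate (median -0.10, camera adjusted p 0.234). PPAR targets were lower for 14 of 22 members with a median of -0.31 (camera adjusted p 0.0383; adjusted p = 0.298 with an estimated correlation), and adjusted over the list alone 1 passed, against 0 over all genes. Plin2, which coats lipid droplets, had 81.1 ± 53.6 and 9.49 ± 4.10 CPM. The PPAR call was lost without vehicle 1 (median -0.37, camera adjusted p 0.110), vehicle 2 (median -0.20, camera adjusted p 0.105), 15-HETrE 1 (median -0.16, camera adjusted p 0.163) or 15-HETrE unnumbered (median 0.04, camera adjusted p 0.132), and its median was -0.53 without vehicle combined and -0.65 without 15-HETrE combined. Ranks (camera adjusted p 0.0634) and the prefix term (median -0.24, camera adjusted p 0.0628) also ended the PPAR call. As means, the immediate early list differed by -0.36 in all libraries, -0.40 within the first prefix and -0.31 within the combined pair. In the same order, the PPAR list differed by -0.48, -0.85 and 0.25. Beside them, the fibroblast markers differed by -3.60 within the first prefix and -0.13 within the combined pair.

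Ribosomal protein genes fell together, 76 of 78 being lower with a median of -0.64 (camera adjusted p 8.8e-24; adjusted p = 0.276 with an estimated correlation). Adjusted over the list alone, 1 passed, against 0 over all genes. Rpl10a, of the large subunit, had 160 ± 2.40 CPM in vehicle and 68.3 ± 6.59 CPM in 15-HETrE libraries, and Rps12, of the small subunit, had 109 ± 1.77 and 48.9 ± 14.5 CPM. Taken for small p, these genes differed by -1.30 and -0.72 within the combined pair, where the mean of the list differed by 0.01. Reads of ribosomal protein genes can be shared with their many processed pseudogenes, so the single values are uncertain. The list differed by -1.02 within the first prefix and by 0.01 within the combined pair, beside the -3.60 and -0.13 of the fibroblast markers. Its mean lay at 7.09 and 7.08 in vehicle 1 and vehicle 2, at 6.42 in vehicle combined and at 6.43 in 15-HETrE combined (log2 scale).

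Transcripts of cells that the sort was meant to leave out were present in every library. The genes with the highest mean included the ribosomal RNA transcript Rn45s, the nuclear RNA Malat1, Slc1a2 and Cdr1. Rn45s took 14.4, 8.79 and 7.35% of the reads in the vehicle libraries and 8.04, 6.47 and 6.23% in the 15-HETrE libraries. Slc1a2, the main glutamate transporter of astrocytes, stood at 655, 369 and 5696 CPM in vehicle 1, vehicle 2 and vehicle combined and at 3025, 980 and 17252 CPM in 15-HETrE 1, unnumbered and combined. Astrocyte markers were higher for 12 of 13 genes, with a median of 1.04 (camera adjusted p 0.0334; adjusted p = 0.696 with an estimated correlation), and 0 passed adjusted over the list alone or over all genes. The astrocyte list differed by 0.93 within the first prefix and by 1.03 within the combined pair, and was higher in both combined libraries, at 7.63 and 8.66, than in the other 4, at 4.93 to 6.09 (mean log2 scale). Its call was lost without vehicle 1 (median 0.60, camera adjusted p 0.298), without vehicle 2 (median 0.35, camera adjusted p 0.480) and without 15-HETrE combined (median 0.11, camera adjusted p 0.436, the test's direction then being down). Its median was 2.04 without vehicle combined and 1.57 without 15-HETrE unnumbered. With the fibroblast level as a covariate, added after the data were seen, the astrocyte call was lost and the direction turned (median -0.35, camera adjusted p 0.176).

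**Figure D2:**
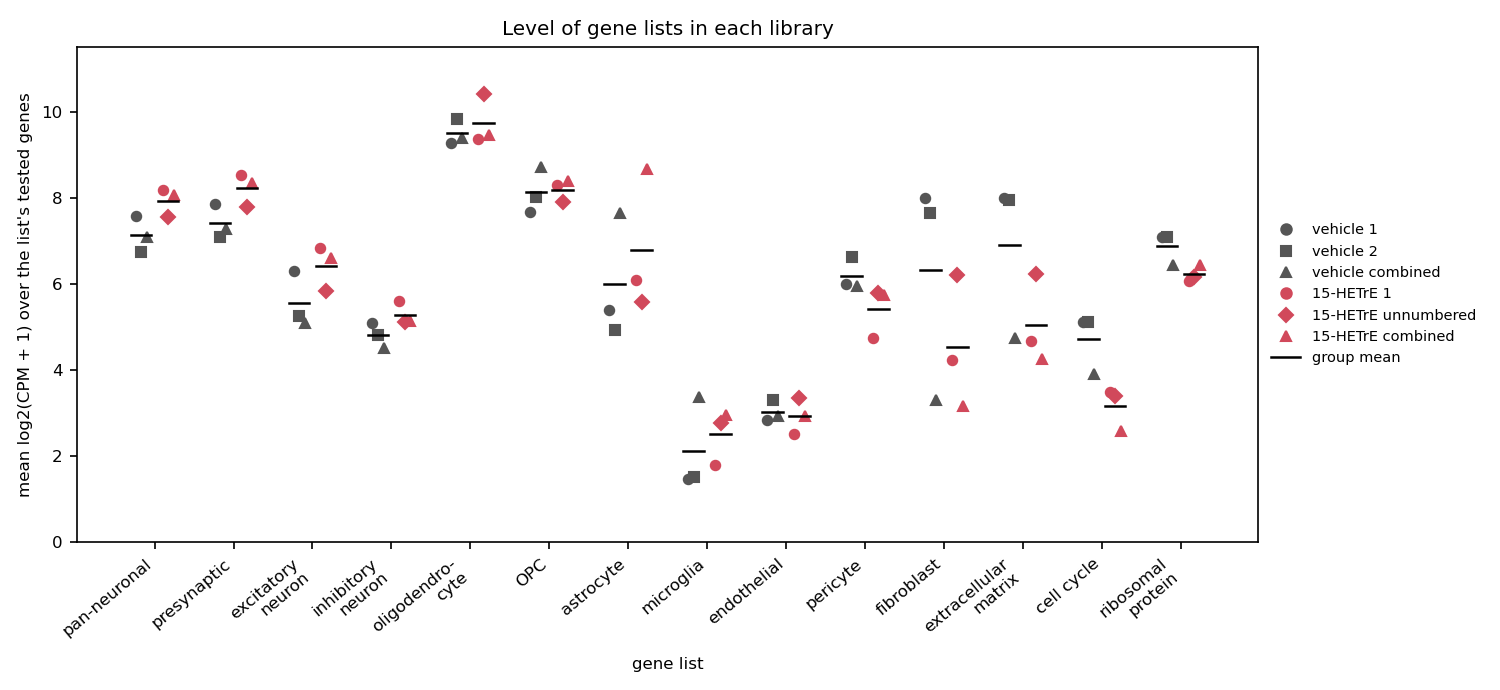
Mean log2(CPM + 1) over the tested genes of 14 gene lists in each of the 6 libraries; grey points are vehicle and red points 15-HETrE libraries, the shape gives the library, and black lines are group means. The fibroblast list lies at 7.99 and 7.63 in vehicle 1 and vehicle 2, at 3.29 in vehicle combined and at 3.15 to 6.19 in the 15-HETrE libraries, and the cell cycle list lies lower in each 15-HETrE library than in any vehicle library.

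Markers of oligodendrocytes, their precursors, microglia and endothelium did not pass. Oligodendrocyte markers had a median of 0.21 (camera adjusted p 0.108), precursor markers 0.08 (camera adjusted p 0.877), microglia and macrophage markers 0.28 (camera adjusted p 0.377) and endothelial markers 0.01 (camera adjusted p 0.999). The oligodendrocyte list stood at 9.28 to 10.4 in the 6 libraries on the log2 scale, and the pan-neuronal list at 6.73 to 8.17. Levels of different genes do not measure the shares of these cells. The precursor list stood at 7.66 to 8.71. Over all genes, and adjusted over the list alone, 0 genes of these 4 lists passed. The oligodendrocyte call appeared without vehicle 2 (median 0.35, camera adjusted p 0.0120), without 15-HETrE 1 (median 0.38, camera adjusted p 0.00807) or without 15-HETrE combined (median 0.34, camera adjusted p 0.0140), and with all 6 libraries from DESeq2's statistics (median 0.24, camera adjusted p 0.0332) or with the fibroblast covariate (median 0.33, camera adjusted p 0.0236). Without vehicle combined, microglia (median 1.23, camera adjusted p 0.00265) and precursor markers (median 0.42, camera adjusted p 0.0189) passed. Microglia markers also passed without both combined libraries (median 1.15, camera adjusted p 0.00504), and precursor markers with library weights (median 0.35, camera adjusted p 0.0420). In an exact two-sided permutation test of each marker list's mean level, 4 of 14 lists reached p = 0.1, the smallest value that 3 against 3 libraries allow, and all 4 had an adjusted p of 0.35. These were the inhibitory neuron, pericyte, lymphocyte and erythrocyte lists, the last pair resting on 1 gene each, Lck and Alas2. For the monocyte and neutrophil and the ependymal lists 2 genes each were kept, too few for the list test.

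The remaining lists did not pass either, with medians between -0.29 and 0.28 over the 12 lists in all. Enzymes that make lipid mediators from polyunsaturated fatty acids had 12 of 21 genes higher and a median of 0.12 (camera adjusted p 0.913). Ptgs2, the inducible cyclooxygenase, had 110 ± 85.0 CPM in vehicle and 20.5 ± 9.04 CPM in 15-HETrE libraries, and Ptges, a prostaglandin E synthase, had 25.2 ± 13.4 and 7.09 ± 8.96 CPM, both with overlapping libraries. Growth factor genes had a median of -0.29 (camera adjusted p 0.155), and adjusted over the list alone 2 passed, against 0 over all genes. Tgfb1 and Igf2 were at 22.5 ± 2.94 and 34.6 ± 3.92 CPM in vehicle and at 3.79 ± 1.23 and 8.43 ± 5.29 CPM in 15-HETrE libraries. Bdnf, a neurotrophin, went the other way, from 2.58 ± 2.14 to 12.7 ± 5.58 CPM with an adjusted p of 0.454 (limma). Genes of p53 signalling and apoptosis had a median of -0.17 (camera adjusted p 0.160), with the cell cycle inhibitor Cdkn1a at 59.4 ± 31.9 and 6.48 ± 4.61 CPM. Genes of glycolysis and hypoxia had a median of -0.07, of cholesterol synthesis 0.18, of histone and arginine modification 0.01, and of nuclear-encoded oxidative phosphorylation 0.02, with camera adjusted p of 0.266, 0.108, 0.931 and 0.888. Genes of complement and antigen presentation had 6 of 13 members higher and a mean log2 fold change of -0.07 (camera adjusted p 0.931). Adjusted over the list alone, 1 gene of the p53 list and 1 of the glycolysis list passed and 0 of the lipid mediator, cholesterol, histone, complement and oxidative phosphorylation lists, against 0 over all genes. Without vehicle combined, the p53 list (median -0.50, camera adjusted p 0.0242) and the cholesterol list (median 0.33, camera adjusted p 0.00456) passed. Both also passed without both combined libraries (camera adjusted p 0.00866 and 0.00765) and with library weights (camera adjusted p 0.0101 and 0.0111), and the cholesterol list with no filter (camera adjusted p 0.0499).

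**Figure D3:**
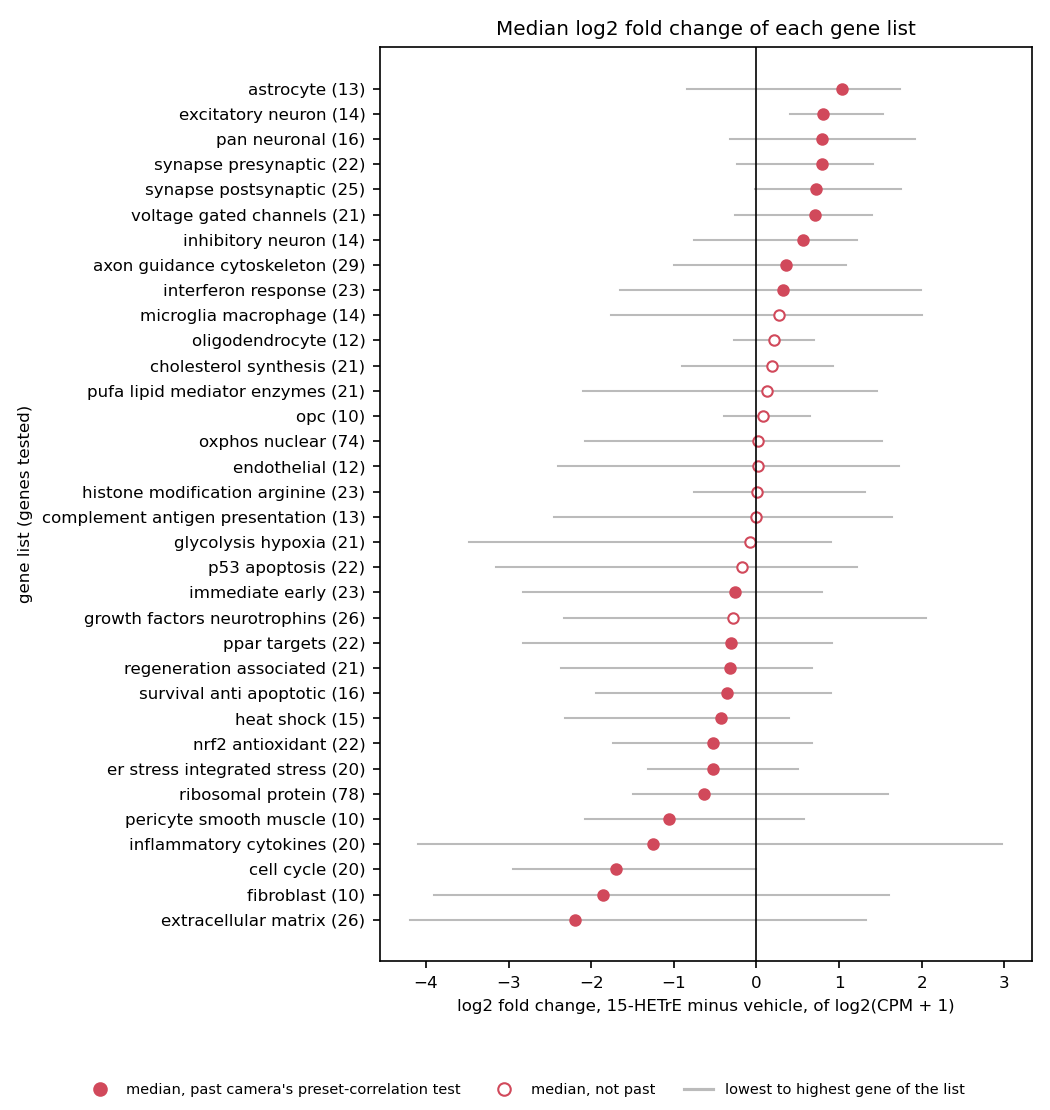
Median log2 fold change (15-HETrE minus vehicle) of each of the 34 gene lists tested, with the number of genes tested in parentheses; filled points passed camera's test with the preset correlation, open points did not, and grey lines run from the lowest to the highest gene of the list. The medians run from -2.20 for the extracellular matrix to 1.04 for astrocyte markers, and 22 lists passed, 9 higher and 13 lower.

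Genes named in advance for the lipid pathway and the sort were near or under the limit of detection, except Thy1. Padi4, a peptidylarginine deiminase (chromosome 4, 140745865 to 140774236), had 0 reads in each of the 6 libraries, which allows up to 0.135 to 0.540 CPM per library, counting error only. Pla2g2e, a secreted phospholipase, had 1 read in 15-HETrE 1 and 0 in the other libraries. Alox15, a lipoxygenase that makes hydroxylated fatty acids, had 9 reads in vehicle 1, 0.421 CPM, and 0 in the others. Of 5 Padi genes listed, Padi2 was kept, at 27.7 ± 5.80 CPM in vehicle and 54.3 ± 23.9 CPM in 15-HETrE libraries with an adjusted p of 0.565 (limma). Thy1, the sort marker (chromosome 9, 44043384 to 44048579), had 156 ± 57.5 and 182 ± 53.1 CPM, a log2 fold change of 0.24 (SE 0.32, adjusted p 0.830, limma), which is within the spread between libraries; it differed by 0.47 within the first prefix and by 0.40 within the combined pair.

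In all, 22 of 34 lists passed camera's test with the preset correlation of 0.01, and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05. By fry, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes, 0 lists passed. Of the 22, 19 had the same sign within the first prefix and within the combined pair; the exceptions were the ribosomal protein, antioxidant and PPAR lists. These lists were called on the same libraries, so a shared sign is no independent evidence. In simulated data of this design with 14523 genes, limma found 0.667, 28.7, 59.3 and 67.3% of genes changed by 2, 4, 8 and 16-fold.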

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

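The batch term for the name prefix, the analysis without both combined libraries, the centring on transcript length or GC content and the fibroblast covariate were tests chosen after the result was seen. The main counts were 0 genes higher, 0 genes lower and 22 lists. Library weights gave 1059 genes higher and 1366 lower, DESeq2 gave 35 and 130, the prefix term gave 1 and 7, and leaving out both combined libraries gave 3 and 201. Leaving out single libraries gave 0 to 2 genes higher and 0 to 108 lower, the highest values being those without vehicle combined. All other settings gave 0 and 0 (limma, or edgeR on recovered reads). The weights favoured vehicle 2 (3.75), 15-HETrE 1 (3.16) and vehicle 1 (1.82) over vehicle combined (0.206), 15-HETrE combined (0.441) and 15-HETrE unnumbered (0.508); apart from this, the cause was not tested.

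The number of lists past camera's test was 18 to 24 when single libraries were left out, 18 with the fibroblast covariate, 20 with the prefix term, 24 without both combined libraries and 20 to 25 in the other settings of camera with a preset correlation or ranks. It was 0 with an estimated correlation and 0 with fry; the first allows for genes of a list moving together, and fry asks another question. The fibroblast covariate ended 5 of the 22 calls (astrocyte, fibroblast, immediate early, reticulum stress and interferon; that of the fibroblast list by construction, since the covariate is its own mean) and brought 1 more (oligodendrocyte), and the prefix term ended 2 (PPAR and interferon). The direction turned for the astrocyte list without 15-HETrE combined (median 0.11, test direction down) and with the fibroblast covariate (median -0.35, against 2.04 without vehicle combined, the highest), and for the astrocyte gene Aqp4 with that covariate (-0.11); the cause was not tested. Marker lists with no overlap between groups numbered 4, and 3 by summed CPM, 4 to 8 when single libraries were left out and 8 without both combined libraries. The Thy1 fold change ran from 0.01 without 15-HETrE 1 to 0.51 without vehicle 1 and passed in no setting.

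No paired analysis was possible because the replicate numbers of the columns of both groups share the number 1 alone; libraries were blocked across groups by the name prefix only, in the batch term above. The low depth of vehicle combined, 5405245 reads, sets the highest floor, 0.540 CPM, so genes at or under it cannot be compared there.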

Other observations

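The count of genes over other splits of the libraries, the tests with the fibroblast covariate or with centring, and the enrichment of lists among DESeq2's calls were tests chosen after the result was seen. DESeq2, which had frequent false calls in simulation, called 130 genes lower that limma and edgeR did not call. They held Ahnak, Msn and Iqgap1, which encode proteins of the cell cortex, at 609 ± 377, 276 ± 127 and 195 ± 64.5 CPM in vehicle and 68.0 ± 20.6, 60.9 ± 21.7 and 59.9 ± 19.8 CPM in 15-HETrE libraries. They also held Hspg2 and Nid2, of basement membranes, at 251 ± 145 and 70.9 ± 51.5 CPM in vehicle and 51.6 ± 17.7 and 9.10 ± 4.61 CPM in 15-HETrE libraries, and Aspm and Bub1b, of mitosis, at 53.7 ± 18.4 and 17.2 ± 1.54 CPM in vehicle and 10.2 ± 4.07 and 2.80 ± 1.09 CPM in 15-HETrE libraries. These genes were picked after their values were seen. No fixed list was enriched among the DESeq2 calls after adjustment; the matrix list came nearest, with 3 of its 26 genes among the lower calls (Fisher's exact p = 0.00157, adjusted p 0.107).

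Matrix and fibroblast transcripts were lower in 15-HETrE libraries. Against transcript length, the matrix median was -2.23 after centring and -2.20 before, which argues against length as its whole cause. A different share of fibroblast-like cells may contribute, if they carry Thy1 and pass the gate, which was not measured here. For the 22 matrix genes not on the fibroblast list the group coefficient was -1.61 (SE 0.95). It became -0.66 (SE 0.20) with the fibroblast level as covariate. The slope on that level was 0.53 (SE 0.05), so the matrix genes moved with the fibroblast markers across libraries. With its SE the group coefficient neither clearly keeps nor clearly loses most of its size. Col1a2 at 2307 CPM in vehicle 1 and 31.8 CPM in vehicle combined shows how far vehicle libraries differ. A lower matrix response to 15-HETrE and a difference in sorting cannot be told apart here.

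Neuronal transcripts were higher in 15-HETrE libraries. Length centring left the median of the 59 neuronal genes at 0.74, from 0.78, which argues against length as the whole cause. Dilution of neuronal RNA by fibroblast-like cells could account for part of it: the group coefficient was 0.80 (SE 0.29) and 0.70 (SE 0.35) with the fibroblast level as covariate. The slope on that level was -0.06 (SE 0.09), and within the combined pair, where fibroblast markers differed by -0.13, the pan-neuronal list differed by 0.97 and the astrocyte list by 1.03. The slope and the combined pair give no sign of dilution, but that pair holds 1 library per group. With 6 libraries the coefficient's SE is too wide to show that most of it was kept. Astrocyte markers, of cells the sort was meant to leave out, rose too. Dilution as a part, a difference in sorting and an effect of 15-HETrE on neurons or their survival cannot be told apart.

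Ribosomal protein transcripts were lower in 15-HETrE libraries. The median of -0.64 was -0.56 after centring on length and -0.64 after centring on GC content, which argues against either as the whole cause. The centring took out the differences of genes outside the lists with like length or GC content, which ran from -0.13 to 0.12 for length and from -0.06 to 0.13 for GC content. The share of fibroblast-like cells may contribute, as the group coefficient went from -0.64 (SE 0.25) to -0.48 (SE 0.24) with the fibroblast level as covariate, and the list differed by 0.01 within the combined pair. This test does not decide, and a biological effect of 15-HETrE stays open.

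Splitting the 6 libraries into 3 and 3 in all 10 ways cannot give a share under 0.05. At an unadjusted p under 0.05 the real split gave 1380 genes, vehicle 1, vehicle 2 and 15-HETrE unnumbered against the rest gave 1815, and vehicle 1, vehicle 2 and 15-HETrE 1 against the rest gave 1155. Past the threshold the real split gave 0 genes, so all 10 splits gave as many, and the highest other split gave 91 genes. The split with 91 also set vehicle 1, vehicle 2 and 15-HETrE unnumbered, the libraries with the most fibroblast transcripts, against the rest. Every other split, with the real one, gave 0 genes. What the 91 genes reflect, and whether they mark a structure of the samples, was not tested. For lists, 1 of the 10 splits, the real one, gave 22, and the highest other gave 17.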
